A study of Mus musculus with 12 samples.

How the data were processed

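The deposited data were 1 table of signal values for mouse gene areas in 12 libraries. The libraries came from DNA immunoprecipitation sequencing, in which sonicated and denatured genomic DNA is pulled down with an antibody before sequencing. Per the labels' protocols, the antibodies were against 5-methylcytosine (5mC), against 5-hydroxymethylcytosine (5hmC, the oxidation product that Tet enzymes make from 5mC) or control IgG. Each of 5 T cell types (naive, Th1, Th2, iTreg and Th17) gave 1 library with the 5mC antibody and 1 with the 5hmC antibody. The Th17 cells also gave 1 IgG library and 1 library of input DNA, which had seen no antibody. Every group therefore held 1 library. The genotype of the cells behind each library was not given in the labels.

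The signal values deposited by the authors are means over each gene area, never negative and rounded to 1 decimal. Per the submitters' processing notes, CASAVA 1.7.0 and the mouse genome build mm9 were used. The aligner settings, the counting step, any fragment extension, any removal of duplicate reads and the scaling between libraries are not given in the sources used here. The read number behind each library is therefore unknown, and neither counting intervals nor detection limits could be computed. The table held 37752 rows with gene identifier, symbol, chromosome, start, end and strand. Coordinates are printed as the file gives them on mm9, and whether they count from 0 or from 1 is not stated. Of the gene identifiers, 31692 were also found in the reference gene table of assembly GRCm38.p6, which was used for names only.

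Column names were matched to libraries by the sample number in the labels' titles, and 0 columns of values were left unused. Where a symbol stood on several rows, the row with the highest mean over the 10 5mC and 5hmC libraries was kept, which left out 208 rows and kept 37544 gene areas. Values were used as deposited. Log2 values were taken after adding 0.2, the 5th percentile of the non-zero values in the 10 libraries, so a log2 difference understates the change of low gene areas. Counts used the 28159 gene areas whose mean over the 10 libraries was at least 3.31, the 25th percentile of those means. The median 5mC value lay only a few rounding steps above 0, so rounding limits the precision of 5mC ratios, above all in low gene areas.

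With 1 library per group, no test between cell types was possible, and differences between cell types have no replicate check. Gene areas were counted by a rule of size, a log2 difference of at least 1 either way, which is 2-fold. The 4 comparisons with naive cells under each antibody share 1 naive library. Lists of genes were fixed from textbook knowledge before the data were examined: signature genes of the 5 cell types; genes of T cell lineage, T cell receptor signalling, JAK and STAT signalling, follicular helper and exhausted T cells, cytokines, cytokine receptors, chemokines, and Tet and Dnmt enzymes with their partners; markers of CD8 T and NK, B, myeloid, erythroid, liver and neuronal cells; housekeeping, cell cycle, imprinted and germline genes; and the olfactory receptor, vomeronasal receptor, Hox, keratin, histone cluster 1, ribosomal protein, interferon alpha, protocadherin beta and beta defensin families. This makes 32 lists. The median of each list was placed among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these libraries. List medians used all members, without the filter on low values, and random lists were not matched on position in the genome. A percentile outside 2.5 to 97.5 was taken to stand apart.

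The 5hmC and 5mC libraries were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend), with cell type as a block and each library centred on its median gene area. A call needed a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1. The spread in this test is that between cell types. The plan had named a count model for the case of read counts and limma for other units. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. On simulated libraries with the spread of these 28159 gene areas, limma recovered 62 of 100 planted log2 differences of 1.5 and 92 of 100 of 3, and called 7 of 27959 unchanged gene areas. For the 5hmC Th1 list step, run on 37544 gene areas, 12 of 200 unchanged lists fell outside the central 95%, and 168 of 200 lists shifted by 0.3 lay above the 97.5th percentile.

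Genes were named by a rule set before the data were examined. It named 19 cytokine, transcription factor, receptor, Tet and Dnmt genes, the 4 largest log2 differences each way in each comparison with naive cells, the 2 largest and 2 smallest members of each list described, and the 6 largest each way between the antibodies. Predicted genes, olfactory and vomeronasal receptors and microRNAs were left out of the second and the last group. Some gene areas that these rules pick are not reported here. Alternatives set in advance were median-ratio scaling between libraries, a pseudocount 4 times as large, no filter on low values, subtraction of the IgG value as deposited, input DNA in place of IgG, random lists matched on length as well, and, for limma, no cell type block, no trend and each cell type left out. The plan had scaled the IgG library before subtraction, but depths are unknown, so IgG was subtracted unscaled. Median-ratio scaling divided each value by a factor of its library before the 0.2 was added. These factors were 3.87 to 4.79 in the 5hmC libraries and 0.21 to 0.26 in the 5mC libraries. This alternative thus also changed the weight of the pseudocount, which grew against 5hmC values and shrank against 5mC values. Further alternatives were added after the data were seen: gene areas of at least 3000 bp alone, lists without the libraries labelled iTreg and Th17, and random lists matched on the naive 5hmC signal. The last uses the same naive library for the matching and for the difference. Noise in that library then lowers the difference of random lists with high naive signal and raises it for those with low naive signal. Percentiles from this matching are biased accordingly.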

Results

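Helper T cells leave the naive state and take on fates with different cytokines: Th1 cells make interferon gamma, Th2 cells make interleukins 4, 5 and 13, Th17 cells make interleukins 17a and 17f, and induced regulatory T cells (iTreg) express Foxp3. The series title ties Tet2, an enzyme that oxidises 5mC, to cytokine expression, and the design set 5mC and 5hmC side by side in 5 such cell types. DNA from each cell type was precipitated with both antibodies, 1 library per cell type and antibody, and Th17 cells also gave an IgG and an input library. The median signal per gene area was 12.0 in the naive 5hmC library and 10.9, 11.0, 11.0 and 9.9 in those labelled Th1, Th2, iTreg and Th17. The 5mC medians lay between 0.6 and 0.7, the IgG median was 0.8 and the input median 1.7. Libraries were therefore centred for the comparison of 5hmC with 5mC, while the comparisons with IgG and input used the values as deposited. The quartiles of the naive 5hmC library were 5.4 and 23.3, wider than the 5.7 and 17.8 of Th1 or the 5.3 and 16.1 of the library labelled Th17. Across gene areas, which are not independent replicates, Spearman's rho between 5hmC libraries was 0.592 to 0.731 for the 4 pairs with naive and 0.721 to 0.792 for the other 6 pairs. Between 5mC libraries it was 0.774 to 0.831. One pair of labels was in doubt: Il17a and Il17f carried most 5hmC signal in the library labelled iTreg, so the 5hmC libraries with these names are called the libraries labelled iTreg and Th17. The labels of the 5mC, IgG and input libraries were not checked, and these libraries are named as labelled.

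Genes that mark naive T cells carried most 5hmC signal in the naive library. All 23 measured members of the naive signature list lay below naive in the mean of the 4 differentiated libraries, 18 of them at least 2-fold, with a median log2 difference of -1.43, below all 10000 matched random lists. Lef1, a transcription factor of naive and immature T cells (chromosome 3, 130813388 to 130926251, mm9), had a 5hmC signal of 127.9 in naive cells and 38.1, 37.8, 40.9 and 22.2 in the libraries labelled Th1, Th2, iTreg and Th17. Satb1, a chromatin organiser of thymocytes, had 77.6 against 20.5, 30.2, 27.9 and 14.2. The smallest differences of the list were at Btla and Dapl1, with log2 differences of -0.67 and -0.61. T cell lineage genes were lower as well, 28 of 28 members, with 17 at least 2-fold lower and a median of -1.09 (percentile 0.02). Within this list Lat, an adaptor of T cell receptor signalling, had 205.7 in naive cells and 30.5 to 64.0 in the others, and Cd3e had 95.6 against 25.8 to 35.9. Tcf12 and Ptpn22 differed least, with -0.18 and -0.31. T cell receptor signalling genes had a median of -1.02 (percentile 0.07), with 18 of 33 at least 2-fold lower. Dgka, a kinase that limits this signalling, was among the lowest, with 110.3 against 27.1 to 39.3, while Jun and Nfatc2 stood at 0.36 and -0.02. Housekeeping genes (-0.83, percentile 0.385), cell cycle genes (-0.64, percentile 1.92) and ribosomal protein genes (-0.31, percentile 0.39) also lay below their random lists. When the random lists were matched on the naive 5hmC signal, an alternative added after the data were seen, the T cell lineage and T cell receptor signalling lists lay at percentiles 46.1 and 51.6, housekeeping and cell cycle genes at 15.5 and 23.4, and the naive signature and ribosomal protein lists stayed low at 0.93 and 0.48. This matching builds a drop into random lists of high naive signal, so percentiles near the middle do not show that the drop is a general one.

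The medians of the Th2 and Th17 signature lists lay above those of gene areas of like signal, while their members went both ways. The Th2 and Th17 signature lists had medians of 0.08 and 0.09 for the mean of the 4 libraries minus naive, at percentiles 98.8 and 98.9 of their random lists, which centred below 0. Above 0 were 13 of 24 and 14 of 27 members. For single libraries minus naive, the Th2 list stood apart in Th1 and Th2 (percentiles 99.1 and 99.5) and not in those labelled iTreg and Th17 (-0.32 and -0.13, percentiles 55.1 and 94.0). The Th17 list stood apart in Th1 and the library labelled iTreg (percentiles 99.1 and 99.96) and not in Th2 or that labelled Th17 (0.09 and -0.50, percentiles 96.7 and 45.5). Members at the upper end were Nfil3, a transcription factor of type 2 immunity, with 15 in naive cells and 69.4, 103.0, 50.2 and 26.8 in the libraries labelled Th1, Th2, iTreg and Th17, and Il24 with a log2 difference of 1.02. At the lower end stood Il17rb and Stat6 (-1.76 and -1.32) in the Th2 list and Il6ra and Nfkbiz (-1.55 and -1.16) in the Th17 list. The Th1 and iTreg signature lists did not stand apart, with medians of -0.48 and -0.27 at percentiles 27.2 and 68.3. Nor did the lists of cytokines (-0.11, percentile 95.2), cytokine receptors (-0.65, 6.56), JAK and STAT genes (-0.78, 6.20), chemokines and their receptors (-0.41, 20.7), follicular helper and exhaustion genes (-0.45, 42.4) or Tet and Dnmt genes (-0.63, 12.2). Markers of other cell types did not stand apart either: CD8 T and NK (-0.04, percentile 83.9), B (-0.21, 64.3), myeloid (-0.34, 38.1), erythroid (-0.16, 62.1), liver (0.07, 89.3) and neuronal genes (0.07, 94.0). With random lists matched on the naive 5hmC signal, the iTreg signature and cytokine lists did stand apart, at percentiles 99.7 and 99.4, beside the Th2 and Th17 signatures at 99.95 and 99.96, and the other lists of this paragraph did not. The bias of this matching may raise such percentiles. The median-ratio factors amount to shifts in log2 difference from naive of 0.17, 0.15, 0.15 and 0.31 for the 5hmC libraries labelled Th1, Th2, iTreg and Th17. The pseudocount weighed more against the scaled values, so low gene areas did not shift by exactly these amounts. Median-ratio scaling turned the medians of the cytokine, CD8 T and NK, and erythroid lists positive. The signs of the naive, T cell lineage, Th1, Th2, Th17 and iTreg lists stayed as given.

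By the rule of size, gene areas with lower 5hmC than naive outnumbered those with higher 5hmC in each of the 4 libraries. Of 28159 gene areas, 1221 were at least 2-fold higher and 4522 lower in Th1, 1366 and 4161 in Th2, 1273 and 4152 in the library labelled iTreg, and 1304 and 7208 in that labelled Th17. The naive library lay at least 2-fold above each of the other 4 in 1725 gene areas and below each in 177. The same counts were 138 and 559 for the library labelled Th17 and between 96 and 165 for those labelled Th1, Th2 and iTreg. The largest differences were mostly in short gene areas. Immunoglobulin kappa segments and a hair keratin-associated gene were highest over naive: Igkj5 (0.5 to 20.3), Igkj4, Defa-ps10 and Krtap8-2 in Th1, Igkv15-101-1 (0.5 to 28.8), Igkj5, Scarna6 and Igkj4 in Th2, Krtap8-2 (0.5 to 16.7), Igkv15-101-1, Tnp1 and Oxt in the library labelled iTreg, and Krtap8-2, Igkv15-101-1, Igkj1 and Rpl27a-ps2 in that labelled Th17. T cell receptor segments were prominent among the lowest: Traj47 (109.5 to 6.9), Trav18 and Snord96a in Th1, Tcra-V8 (32.8 to 1.3), Trav7-5 and Traj47 in Th2, Traj47, Tmem210 and Trbv24 (25.6 to 1.8) in the library labelled iTreg, and Trav18, Trbv13-1 (52.4 to 1.6), Ighv3-6 and Mocs3 in that labelled Th17. Such segments are cut out or joined in rearranging lymphocytes, but whether this bears on the differences was not tested. Short gene areas give less precise means: Igkj5, Igkj4 and Igkj1 have a length of 37 bp each and had naive values of 0.5, 0.7 and 2.4. Igkv15-101-1 also had an IgG signal of 7.8. In gene areas of at least 3000 bp, an alternative added after the data were seen, Nfil3 (15 to 103.0) and Batf3 (13.5 to 55.9) were among the 4 highest over naive in Th2, and Il25 (IgG signal 20.5), Il17f and Il17a in the library labelled iTreg. The counts moved with scaling: under median-ratio scaling they were 1503 higher and 2853 lower in Th1, 1623 and 2772 in Th2, 1520 and 2684 in the library labelled iTreg, and 2341 and 4367 in that labelled Th17.

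**Figure D1:**
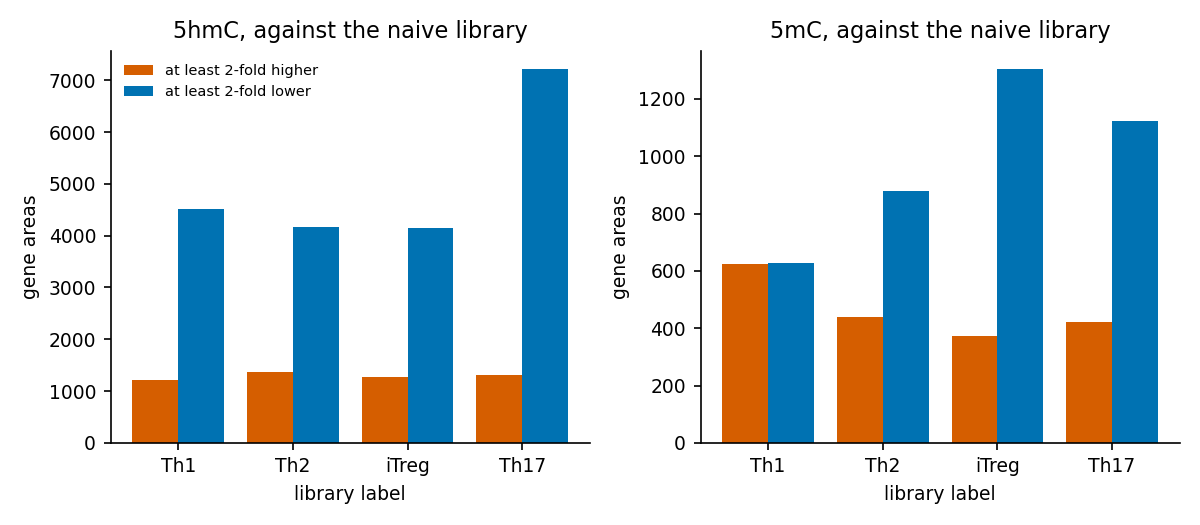
Bars give the number of gene areas, of 28159, with signal at least 2-fold higher or lower than in the naive library, for 5hmC (left) and 5mC (right) and for each library label (horizontal axis); the vertical scales differ. Lower 5hmC exceeded higher 5hmC in all 4 libraries, from 4152 against 1273 to 7208 against 1304.

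Signature genes of Th2 cells carried more 5hmC in the Th2 library than in the mean of the other 4, and those of Th1 cells in the Th1 library less clearly. The Th1 list had a median log2 difference of 0.23 between the Th1 library and the mean of the other 4 (percentile 99.99), with 17 of 22 members above 0 and 2 at least 2-fold higher. Tbx21, which encodes the Th1 factor T-bet (chromosome 11, 96959320 to 96976644), had 54.8 in Th1 against 21.7 in naive, 34.9 in Th2 and 20 and 18.4 in the libraries labelled iTreg and Th17. Gzmb, a cytotoxic granule protease, was the other, with 35.1 against 14.2 to 18.9. Ifng (chromosome 10, 117878102 to 117882947) had 22.6 in Th1 against 8.9 to 14.3 elsewhere. At the other end of the list stood Tnf and Cxcr6 (-0.19 and -0.51). Without the libraries labelled iTreg and Th17, added as an alternative after the data were seen, the Th1 median was -0.02 (percentile 94.97), so it rested on those libraries. Against naive cells alone the Th1 median was -0.25, with 16 of 22 members below 0. The Th1 library also stood apart for the Th17 and Th2 lists (0.18 and 0.06, percentiles 99.97 and 97.7) and the Th2 library for the Th17 list (0.19, percentile 98.7), so the higher values were not limited to the own list. The Th2 list had a median of 0.33 (percentile 99.99), with 20 of 24 members above 0 and 7 at least 2-fold higher. Il4 (chromosome 11, 53425961 to 53432166) had 82.6 in Th2 against 20.2 to 26.2, Il5 had 40.6 against 11.1 to 25.2, and Il13 had 69.0 against 22.1 to 38.8. Il10 had 51.7 in Th2, 29.3 in Th1 and 8.1 to 24.2 elsewhere. Il17rb and Il6 were lowest (-0.67 and -1.05). Gata3, the Th2 master regulator, had 75.2 in Th2, below the 194.9 of the library labelled iTreg and the 99.6 of naive cells, and its IgG signal was 15.1. Without the libraries labelled iTreg and Th17 the Th2 median was 0.26 (percentile 99.9).

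Signature genes of iTreg and Th17 cells did not carry more 5hmC in the libraries with their labels. The iTreg list had a median of -0.12 in the library labelled iTreg (percentile 8.52), with Nt5e and Ctla4 highest (0.72 and 0.33) and Tnfrsf4 and Tnfrsf18, both receptors of the tumour necrosis factor family, lowest (-0.68 and -1.40). Foxp3 (chromosome X, 7156818 to 7172359) had 25.3 there, 30.9 in the library labelled Th17, 24.2 in naive cells, 16.9 in Th2 and 13.0 in Th1. Il2ra had 48.6 against 39.2 to 70.5, and Ctla4 35.0 against 20.4 to 41.0. The Th17 list had a median of -0.63 in the library labelled Th17 (percentile 0.14), where 24 of 27 members lay below 0. Il17a (chromosome 1, 20720985 to 20724576) had 8.8 in that library and 31.3 in the library labelled iTreg, with 4.3 to 10.8 in the other 3. Il17f, its neighbour (20767226 to 20774350), had 5.3 and 32.8, with 7.6 to 13.0 in the other 3. Tmem176a and Tmem176b were lowest in the library labelled Th17 (-2.01 and -2.27), and Maf was among the highest (0.09). Il21 had 37.8 there and 59.6 to 82.2 elsewhere. The library labelled Th17 was also low for the T cell lineage, T cell receptor signalling and cell cycle lists, with medians of -0.73, -0.72 and -0.69 against the other 4 at percentiles 0.03, 0.03 and 0. So were the naive signature (-0.88, percentile 0), Th2 signature (-0.66, percentile 0.16) and cytokine receptor lists (-0.60, percentile 0.24), but not for the Th1 signature, iTreg signature or CD8 T and NK lists (percentiles 11.0, 12.0 and 35.6).

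**Figure D2:**
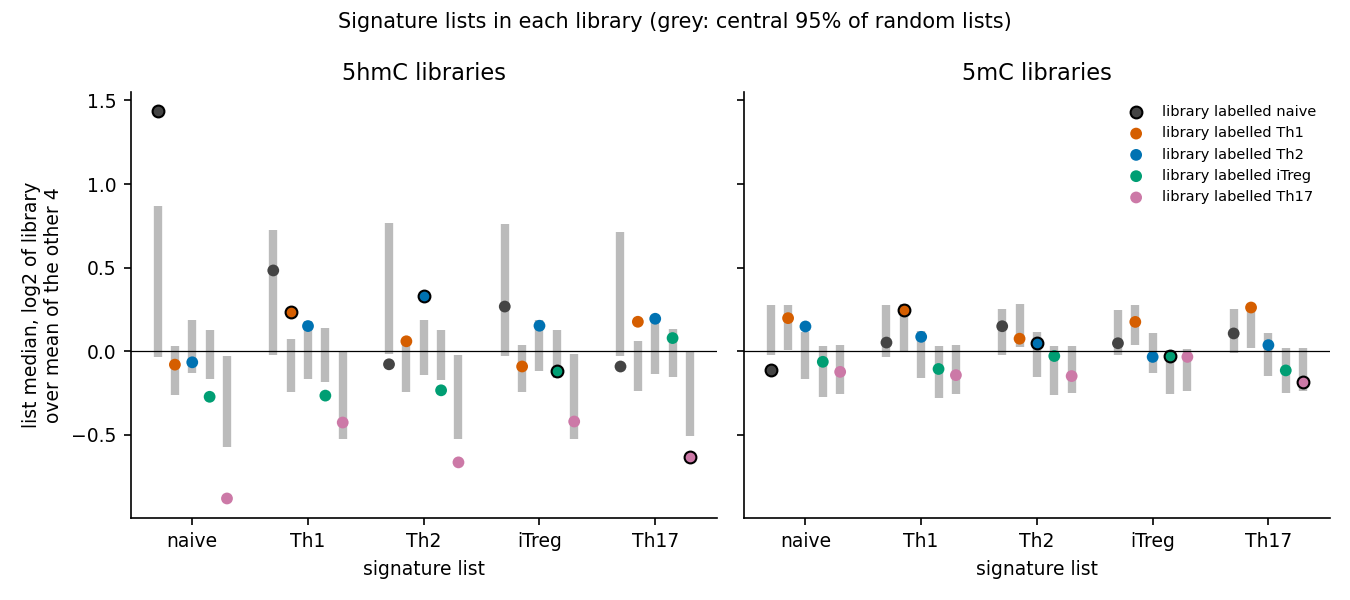
Points give the median log2 signal of a library over the mean of the other 4, for the 5 signature lists (horizontal axis) and for 5hmC (left) and 5mC (right); outlined points mark the library whose label matches the list, and grey bars span the central 95% of 10000 matched random lists. With 5hmC, the naive, Th1 and Th2 lists lay above their bars in their own libraries (1.43, 0.23 and 0.33), and the Th17 list lay below its bar in the library labelled Th17 (-0.63).

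**Figure D3:**
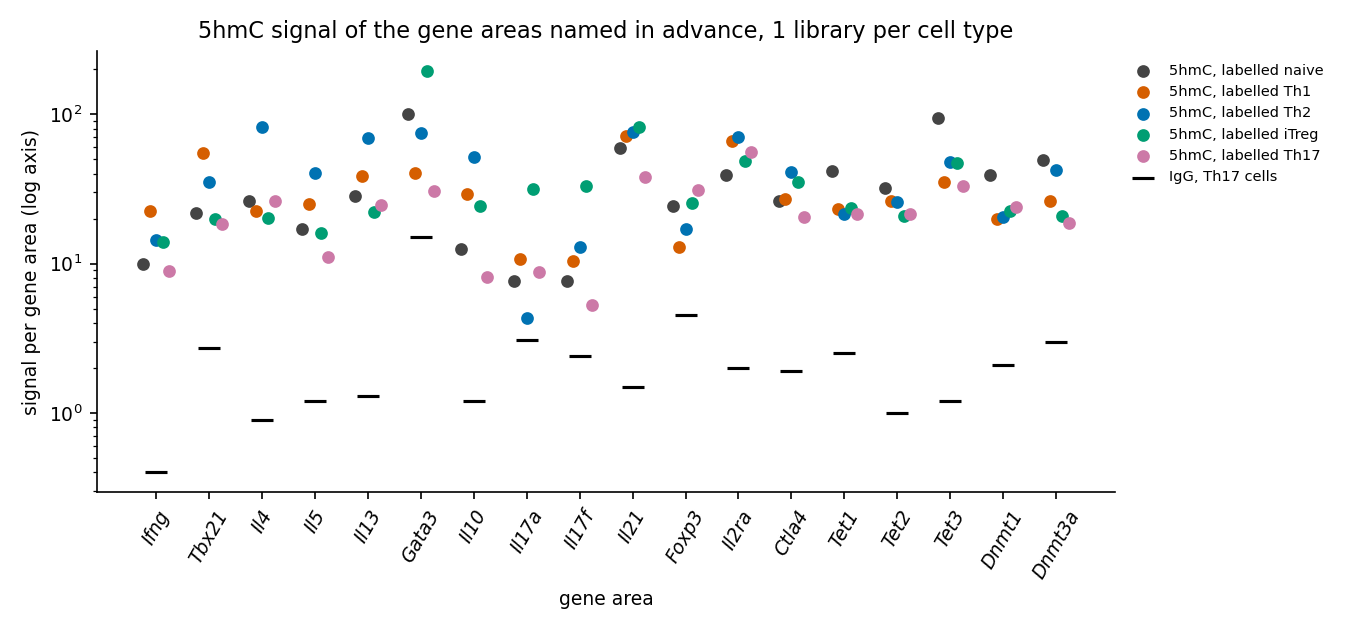
Points give the 5hmC signal (log axis) of 18 gene areas in the 5 libraries, 1 library per cell type, and black dashes the IgG signal in Th17 cells. Il4 was highest in Th2 (82.6), Tbx21 in Th1 (54.8), and Il17a and Il17f in the library labelled iTreg (31.3 and 32.8).

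The genes of 5 Tet and Dnmt enzymes had their highest 5hmC in naive cells and Dnmt3b its lowest, while the whole list of Tet and Dnmt genes did not stand apart. Tet1 had 41.4 in naive cells against 21.5 to 23.6 in the other 4 libraries, Tet3 94.3 against 32.9 to 48.0, and Dnmt1, the maintenance methyltransferase, 38.9 against 19.9 to 24. Tet2 had 31.9 against 20.8 to 26.3 and Dnmt3a 49.0 against 18.8 to 42.5. Dnmt3b had 162.5 in naive cells and 215.8 to 339.7 in the others, but its IgG signal was 326.1. Idh2, whose product feeds Tet enzymes, had the lowest difference of the Tet and Dnmt list (-1.46), and Gadd45a stood near 0 (0.08).

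With 5mC, naive signature genes and cytokine receptors carried relatively more signal after differentiation, but the differences were small. The naive signature list had a median of 0.11 for the mean of the 4 libraries minus naive (percentile 99.9), with 15 of 23 members above 0. Lef1 had 0.5 in naive cells and 0.8 to 1.0 in the others, and Tcf7 0.4 and 0.5 to 0.9, while Sox4 and Dapl1 stood at -0.22 and -0.28. Cytokine receptor genes had a median of 0.12 (percentile 100), led by Il6st and Il2rg (0.62 and 0.52), with Il9r and Il2rb lowest (-0.36 and -0.37). T cell receptor signalling genes (0.04, percentile 99.5), T cell lineage genes (0.02, percentile 98.2) and chemokine genes (0.05, percentile 98.9) also stood apart from their random lists. None of the members of these 5 lists reached 2-fold. The list medians are small against the rounding to 1 decimal at such low values. Across gene areas, Spearman's rho with Th17 input DNA was 0.489 to 0.519 for the 5mC libraries and 0.365 to 0.454 for the 5hmC libraries. The values as deposited do not show whether the 5mC antibody enriched over input. These differences in signal therefore need not be changes in methylation. The signature lists of Th1, Th2, iTreg and Th17 cells did not stand apart in their own 5mC libraries, with medians of 0.24, 0.05, -0.03 and -0.19 at percentiles 91.9, 80.7, 92.4 and 12.1. The 5mC signal was 0.7 to 1.1 at Ifng in naive, Th1, Th2 and iTreg cells and 0.4 in Th17 cells, 1.1 to 1.5 at Il4, 0.3 to 1.1 at Il17a and 0.7 to 1.3 at Foxp3.

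By the rule of size, 624 gene areas had at least 2-fold higher 5mC than naive and 627 lower in Th1, 438 and 879 in Th2, 374 and 1303 in iTreg, and 422 and 1123 in Th17. The median lengths of these gene areas were 576 to 821 bp. In gene areas of at least 3000 bp, added after the data were seen, at most 45 were higher and 173 lower in any of these libraries, of 20021. The replication-dependent histone gene Hist2h4 was the highest or second highest over naive in each, with 0.3 in naive cells and 2.5 to 3.5 in the others. Small nucleolar RNA genes and pseudogenes made up much of the rest, such as Snord85 (0.3 to 3.7 in Th1) and Rpl28-ps2 (1.4 to 7.0 in Th2). Among the lowest were Igkj4 (2.7 in naive cells and 0.1 to 0.2 in Th1, iTreg and Th17), Ighv3-6 in Th2 (1.9 to 0.1), Snora23 in iTreg and Th17 (2.6 to 0.1 in both), and Krtap22-2 in Th17 (4.8 to 0.2). The median-ratio factors amount to shifts in 5mC difference from naive of -0.01, 0.15, 0.26 and 0.24 in Th1, Th2, iTreg and Th17. The pseudocount weighed less after this scaling, so low gene areas moved by other amounts, some the opposite way. With 4 times the pseudocount the counts were 152 higher and 172 lower in Th1 and 116 and 257 in Th2. They were 99 and 365 in iTreg and 107 and 277 in Th17. After subtracting IgG the counts were 1310 and 1000 in Th1 and 778 and 1667 in Th2. They were 638 and 2392 in iTreg and 599 and 2212 in Th17. The IgG median of 0.8 lay above the 5mC medians of 0.6 to 0.7. Unscaled subtraction thus leaves little or no 5mC signal in many gene areas, and the counts after it are a weak check. With median-ratio scaling the counts were 1052 higher and 1102 lower in Th1, 1007 and 1328 in Th2, 1095 and 1493 in iTreg, and 1110 and 1323 in Th17. This scaling turned the 5mC medians of 11 lists from below 0 to above 0, among them those of the Th1, Th17 and iTreg signatures, and the naive signature, cytokine receptor and T cell lineage lists stayed above 0.

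Most T cell lineage genes carried more 5hmC relative to 5mC than the median gene area. With limma over the 5 cell types, 10420 of 28159 gene areas passed an adjusted p of 0.05, of which 2853 had 5hmC at least 2-fold higher and 2147 lower than 5mC after centring. Without the filter on low values, which rests mostly on the larger 5hmC values, the limma counts were 3607 higher and 6035 lower, so which direction held more gene areas depended on the filter. Of the T cell lineage genes, 25 of 28 were higher and 0 lower. Cd27, a costimulatory receptor, had a log2 difference of 2.66 (SE 0.31, limma adjusted p = 0.0005011, higher in 5 of 5 cell types), and Cd2 of 2.59 (SE 0.19, limma adjusted p = 0.0001236, 5 of 5). Fyn and Txk were at the lower end, with 0.74 each. Higher 5hmC was also called in 18 of 23 naive signature genes, 24 of 33 T cell receptor signalling genes, 20 of 35 cytokine receptor genes, 11 of 17 follicular helper and exhaustion genes, 14 of 27 iTreg, 12 of 27 Th17, 10 of 24 Th2 and 7 of 22 Th1 signature genes. It was called in 13 of 45 cytokine genes, 8 of 23 chemokine genes, 8 of 18 JAK and STAT genes, 3 of 21 Tet and Dnmt genes and 4 of 16 CD8 T and NK genes. Of the genes of other lineages, 3 of 18 B cell, 3 of 20 myeloid, 0 of 12 erythroid, 1 of 15 liver and 2 of 19 neuronal genes had higher 5hmC. The differences between these counts were not tested. Housekeeping genes had 7 of 27 higher and 3 lower, and cell cycle genes 4 of 32 and 0. All these counts were equal when adjusted over the list alone.

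The 9 protocadherin beta genes tested, of 22, carried relatively more 5mC than the median gene area, and the other members did not pass the filter. All 9 had lower 5hmC than 5mC, with a median of -1.35. Lower 5hmC was called in 8 of 24 histone cluster 1 genes, 35 of 229 ribosomal protein genes and pseudogenes (36 adjusted over the list alone), 48 of 490 olfactory receptor genes (47 adjusted over the list alone), 6 of 49 keratin genes, 5 of 25 imprinted genes, 4 of 22 germline genes and 4 of 15 liver genes. Higher 5hmC was called in 2, 15, 18 (16 adjusted over the list alone), 5, 3, 0 and 1 of them. In the same order the list medians were 0.22, -0.11, 0.02, -0.20, -0.12, -0.43 and -0.17, so these lists did not share the lean of the protocadherin beta genes. Of all gene areas tested, 7.6% were called lower and 10.1% higher. The differences from these shares were not tested. Only members past the filter were tested, such as 24 of 56 histone cluster 1 genes and 490 of 1419 olfactory receptor genes. Hox genes had 8 of 35 higher and 2 lower, vomeronasal receptors 5 of 70 and 0, interferon alpha genes 3 of 8 and 0, and beta defensins 8 of 34 and 1. Among single gene areas the largest positive differences were at Tor2a (5.17), the overlapping Ttc16 (4.47), Dnmt3b (3.80), the transcription factor gene Jund (3.40), the chemokine receptor gene Ccr8 (3.24) and Pnrc1 (3.12, SE 0.15, limma adjusted p = 5.325e-05, 5 of 5 cell types). The IgG signal was 107.9 at Tor2a, 54.3 at Ttc16 and 326.1 at Dnmt3b, against 1.5, 0 and 0.4 at Jund, Ccr8 and Pnrc1. The largest negative differences were at the histone genes Hist1h4a (-5.79), Hist1h3d (-5.22) and Hist1h2aa (-3.84), the retrogene Rps4y2 (-3.95), Vhl-ps1 (-3.85) and the testis gene Actl7b (-3.72, SE 0.19, limma adjusted p = 5.325e-05, lower in 5 of 5 cell types). The IgG signal of these gene areas was 4.8 at Hist1h4a, 0.2 at Hist1h3d and Hist1h2aa, 1.1 at Rps4y2, 0 at Vhl-ps1 and 4.1 at Actl7b. At Actl7b the means over the cell types, 3.96 with 5hmC and 3.56 with 5mC, lay below IgG in the values as deposited. The 5 cell types stand in for replicates here, and whether they came from separate animals is not stated.

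Background was measured in Th17 cells alone. The 5hmC signal of the library labelled Th17 was at least 2-fold above IgG in 27413 of 28159 gene areas (97.4%). The 5mC signal was at least 2-fold above IgG in 5490 and below it in 7964, and against input DNA in 143 and 16803. The scales of these libraries are not given, so these counts depend on the scaling: with median-ratio scaling 9559 gene areas had 5hmC and 9042 had 5mC at least 2-fold above IgG. Dnmt3b, a de novo methyltransferase gene (chromosome 2, 153475189 to 153513465) had an IgG signal of 326.1 and an input signal of 2.0. Its 5hmC signal in the library labelled Th17, 308.6, was below that of IgG in the values as deposited.

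**Figure D4:**
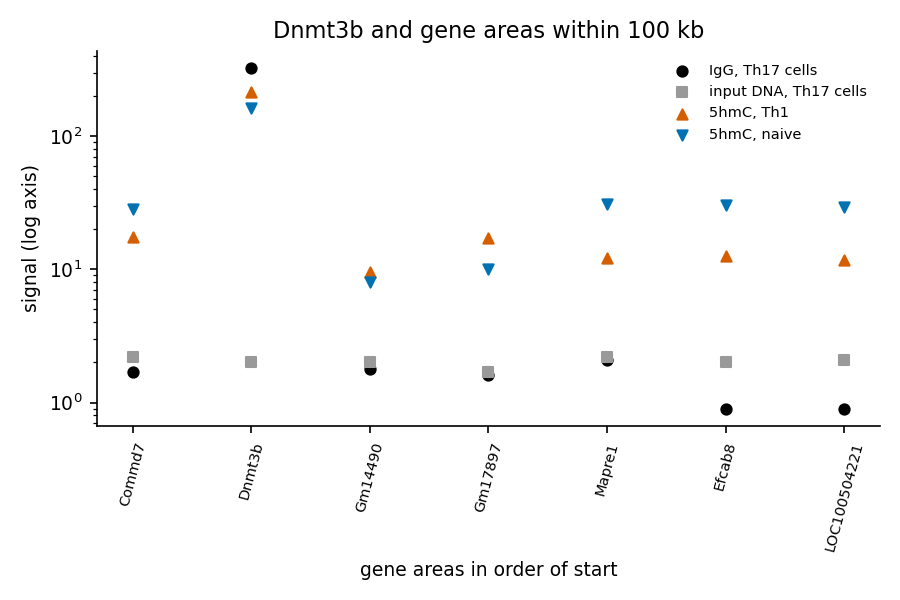
Points give the signal (log axis) of Dnmt3b and the gene areas within 100 kb that do not overlap it, in the order of their start, for the IgG and input libraries of Th17 cells and the 5hmC libraries of Th1 and naive cells. IgG reached 326.1 at Dnmt3b, and 2.1 or less at the other gene areas.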

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

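All tests of an explanation in this part were chosen after the results were seen. Among 38 sets of 5 libraries (19 genes named in advance, 2 antibodies), 7 had 1 library far from the other 4. About 1 in 20 would by chance if values were normal and the sets independent. They are not independent, since all sets under an antibody share the same libraries. The naive 5hmC library stood apart in 1902 gene areas, against 239 to 697 for the other 4. The count of 7 can therefore not be set against chance. Il4 had a 5hmC signal of 82.6 in Th2, with 26.2 as the next highest. Tet1, Tet3 and Dnmt1 had 41.4, 94.3 and 38.9 in naive cells, with 23.6, 48 and 24 next. Il17a and Il17f had 31.3 and 32.8 in the library labelled iTreg, with 10.8 and 13 next, and the 5mC signal of Il17f was lowest in the iTreg library, at 0.3 with 0.6 next. Outside the comparisons of cell types, IgG gave 326.1 at Dnmt3b, where input DNA gave 2. The liver, keratin and beta defensin lists lay above naive in all 4 differentiated 5hmC libraries and below naive in all 4 5mC libraries, with median log2 differences of 0.07, 0.31 and 0.42 for 5hmC and -0.24, -0.23 and -0.24 for 5mC. This difference was not tested.

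The Th17 signature list lay at percentile 99.98 for the library labelled iTreg minus that labelled Th17, and Il17a and Il17f were 3.56-fold and 6.19-fold higher. If these 5hmC libraries carried each other's label, the iTreg list would be expected low in the same difference, but it lay at percentile 87.15, neither low nor high enough to decide, so a swap cannot be told apart from correct labels by these lists. A low signal of the library labelled Th17 at T cell lineage genes in general may account for the list, because the T cell lineage list, which shares no gene with it, lay at percentile 99.64. It did not account for Il17a and Il17f, which in the library labelled iTreg stood at least 2.52-fold above the highest of the naive, Th1 and Th2 libraries. A single wrong label, and 5hmC gained at these genes in iTreg cells, stay open and were not tested. Nor was it tested whether the iTreg and Th17 labels hold for the 5mC, IgG and input libraries.

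The Dnmt3b signal argues against 5hmC as its main source, since IgG, which binds neither mark by design, was 163.1-fold above input DNA there. Extra genomic copies or repeats would raise input DNA, which was 1.18 times its median gene area, though input was measured in Th17 cells only. Short stretches of this gene present as foreign DNA, such as plasmids or PCR products, were a further candidate. The 6 neighbouring gene areas within 100 kb had a median IgG signal 2.06 times that of the median gene area, and 0 of them exceeded 10. Low neighbours would follow from any focal signal, so they do not single out foreign DNA. Foreign DNA present in the sample before precipitation would also raise input DNA, which was near its median gene area. The 5mC signal of Dnmt3b was 0.7 to 1.2 in the 5 cell types. Focal binding by IgG was not tested, and no biological explanation was tested.

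The lower 5hmC signal of T cell lineage genes after differentiation lay at percentile 46.07 among random lists matched on the naive signal. Gene areas with a high value in this 1 naive library tend to lie lower in the others by noise alone. A drop is thus built into these random lists, and the percentile cannot show that the lineage genes share a general drop. The naive signature list lay at 0.93 in the same test, below such gene areas. With median-ratio scaling the naive signature list kept a naive excess of 1.22 on the log2 scale. The factors of this scaling amount to shifts of only 0.15 to 0.31 in 5hmC differences from naive, so the outcome was fixed in advance and does not test scaling. A scaling factor shifts gene areas well above the pseudocount nearly alike and so bears little on a percentile among random lists. A wider range of the naive library, as a different efficiency of precipitation may give, and a loss of 5hmC in the differentiated cells cannot be separated for the lineage list with 1 library per cell type. For the naive signature list a difference between the cell types stays open, as a hypothesis.

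For 5hmC against 5mC, the libraries are paired by cell type, and 16 splits of the 10 libraries part all 5 pairs, the real one included, too few for a share under 0.05. The real split gave 2853 gene areas with higher and 2147 with lower 5hmC, 1 of the 16 gave as many, and the highest count of the other splits was 0 in both directions. Those other splits turn some pairs round, which adds the difference between antibodies to the spread. Their counts of 0 are therefore little guide to chance. Most of 100 splits drawn without regard to pairs put both antibodies of a cell type in 1 group, which adds the difference between antibodies to the spread, and apart from the real split they gave 0 as well.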

How the results depend on the processing

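The alternatives with gene areas of at least 3000 bp and without the libraries labelled iTreg and Th17 were added after the data were seen. Over all alternatives, 79 values for the planned comparisons stayed within 1.5 times (counts) or within 1 SD of the random lists (medians), 70 moved beyond that and 1, a median that stood apart from its random lists, changed sign. Among medians that did not stand apart, the 5mC iTreg median turned positive with median-ratio scaling and the 5mC Th2 median turned to -0.0101 without the libraries labelled iTreg and Th17. For the counts of the other 4 libraries standing apart, 7 stayed and 17 moved. For 5hmC against 5mC, higher counts stayed between 2402 and 3607, and leaving out each cell type gave 2716 to 2994 higher and 2069 to 2212 lower; without a filter the lower count was 6035. The cause was not tested where the construction does not show it.

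With median-ratio scaling, lower 5hmC than naive was counted in 2853 (Th1), 2772 (Th2), 2684 (labelled iTreg) and 4367 (labelled Th17) gene areas, and higher in 2341 (labelled Th17). The naive library stood apart in 1182 with 5hmC and 305 with 5mC. Higher 5mC was counted in 1052, 1007, 1095 and 1110 for Th1, Th2, iTreg and Th17, and lower in 1102 (Th1) and 1328 (Th2). Counts over IgG were 9559 (5hmC) and 9042 (5mC). List medians were -0.42 (5hmC, Th17), -0.28, 0.11, 0.13 and -0.0751 (5mC, naive, Th1, iTreg and Th17).

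With 4 times the pseudocount, 5mC counts for Th1, Th2, iTreg and Th17 were 152, 116, 99 and 107 higher and 172, 257, 365 and 277 lower. The naive 5mC library stood apart in 38, 2158 exceeded IgG, and the 5mC Th1 list median was 0.15. Without a filter on low values, more gene areas were tested: higher 5hmC was counted in 2762, 2808, 2760 and 2734, higher 5mC in 1108, 815, 690 and 805, lower 5mC in 1303, 1738, 2416 and 2057, and the naive 5mC library stood apart in 355. After subtracting IgG, 5mC counts were 1310, 778 and 638 higher (Th1, Th2, iTreg) and 1000, 1667, 2392 and 2212 lower. With input DNA in place of IgG, 143 gene areas had higher 5mC. In gene areas of at least 3000 bp, which are fewer, 5hmC counts were 329, 474, 358 and 401 higher and 2854, 2513 and 2547 lower (Th1, Th2, labelled iTreg), and 5mC counts 45, 24, 32 and 19 higher and 34, 86, 173 and 141 lower. Without the libraries labelled iTreg and Th17, the 5hmC naive median was 1.15, the 5mC naive median -0.26, and the 5hmC Th1 median changed sign, to -0.0239.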

Other observations

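The test of an explanation in this part was chosen after the result was seen. Keratin, protocadherin beta, beta defensin, olfactory and vomeronasal receptor lists lay above their random lists in 5hmC after differentiation. Their medians used all members, also those below the filter on low values. Past that filter were 9 of 22 protocadherin beta, 490 of 1419 olfactory and 70 of 325 vomeronasal receptor genes. The same held for 49 of 51 keratin genes and 34 of 42 beta defensins. Random lists were drawn without regard to position, so linked members of a family counted as separate, and these percentiles may overstate the difference. Keratin genes had a median log2 difference of 0.31 for the mean of the 4 differentiated libraries minus naive, above all 10000 random lists, with 40 of 51 members above 0. Krt6b had 3.6 in naive cells and 6.5 to 14.0 in the others, and Krt79 5.9 and 12.2 to 16.9, while Krt222 and Krt82 had -0.81 and -0.92. Protocadherin beta genes had a median of 0.57 (percentile 99.9; Pcdhb17 and Pcdhb18 highest at 1.31 and 1.19, Pcdhb11 and Pcdhb4 lowest at -0.22 and -0.68) and beta defensins of 0.42 (percentile 100; Defb18 and Defb20 highest at 1.51 and 1.29, Defb30 and Defb12 lowest at -0.47 and -0.60). Olfactory and vomeronasal receptors had 0.20 and 0.28, both at percentile 100. Median-ratio scaling kept these signs. When the random lists were matched on the naive 5hmC signal, keratin genes and beta defensins stayed at percentile 100, and protocadherin beta, olfactory and vomeronasal receptor genes lay at 97.1, 63.6 and 81.0. The bias of this matching, given with the methods, holds for all lists of this paragraph. Imprinted (-0.03, percentile 90.5), germline (0.03, 91.5), Hox (-0.04, 87.3), interferon alpha (0.21, 90.3) and histone cluster 1 genes (-0.18, 3.43) did not stand apart, although histone cluster 1 genes lay at 0.01 when matched on the naive 5hmC signal, and median-ratio scaling turned the imprinted and Hox medians positive.

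Imprinted genes had lower 5mC signal in the mean of the 4 differentiated libraries than in the naive library, a difference between single libraries. Their median was -0.28 for the mean of the 4 libraries minus naive (percentile 0.585), with 22 of 27 below 0, and -0.36 for iTreg against the other 4 (percentile 0.03). Gene areas past the filter also had median log2 differences from naive of 0, -0.11, -0.19 and -0.19 in Th1, Th2, iTreg and Th17. The count below 0 thus partly follows the level of the libraries. Peg10, a paternally expressed gene, had a 5mC signal of 1.9 in naive cells and 0.9 to 1.4 in the others, and Ndn had 1.3 and 0.3 to 1.0. Inpp5f and Grb10 were highest, at 0.12 and 0.09. With 5mC, keratin and olfactory receptor genes were also lower (-0.23, percentile 0.32, and -0.19, percentile 0). Median-ratio scaling kept these 3 signs, with medians of -0.17 for imprinted, -0.12 for keratin and -0.24 for olfactory receptor genes.

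The median signal on chromosome X was 0.433 to 0.553 of the autosomal median in the 5hmC libraries, 0.429 to 0.571 in the 5mC libraries, 0.375 with IgG and 0.765 in input DNA. The chromosome X medians behind these ratios were 0.3 to 0.4 with 5mC and 0.3 with IgG, rounded to 1 decimal. The 5mC and IgG ratios are therefore coarse, and differences among them or from the 5hmC ratios are not resolved. The 64 gene areas on chromosome Y had a median of 0 in all 12 libraries.

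T cell receptor delta segments lie inside the alpha locus and are cut out when alpha genes rearrange. The lists of delta and gamma gene areas were formed after such segments had been seen among the lowest. Across 11 delta gene areas the median 5hmC signal was 8.7 in naive cells and 1.4, 1.6, 0.9 and 0.5 in the libraries labelled Th1, Th2, iTreg and Th17. Trdc had 19.9 against 0.5 to 3.3 with 5hmC and 0.6 against 0 to 0.1 with 5mC, and its input signal in Th17 cells was 0.1. The 13 gamma gene areas did not stand apart with 5hmC (percentile 24.2). A hypothesis is that the naive sample held more cells that keep the delta locus, which may raise both marks there. With 5mC the delta list lay at percentile 0.24, but its median of 0.1 in naive cells and 0 in the others is 1 rounding step, so this could not be decided without input DNA of naive cells.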
